A study of Mus musculus with 15 samples.

How the data were processed

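Total RNA from spleens of Bl/6 Taconic mice with acute promyelocytic leukaemia was extracted with Trizol, amplified from 20 ng, labelled with biotin and hybridised to Affymetrix Mouse Exon 1.0 ST arrays, per the labels' protocols. This platform reads each gene through several probesets, most of which lie in single exons. The authors deposited 1 intensity per probeset and array, on a linear scale from 2.38 to 19380.5. RMA, which corrects background, normalizes between arrays and summarises probes, and the genome build mm9 are named without a version in the submitters' processing notes. The linear scale was settled from the values; all are positive, so no centring was seen, and a 1-colour array has no direction. Scanner files were not analysed here, so background correction could not be varied and scan date could not be checked.

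The median deposited intensity per array was 121 for tumor_9504, 129 for tumor_31, 124 for tumor_9495, 124 for tumor_9523, 125 for tumor_9500, 108 for tumor_9509, 124 for tumor_9492, 122 for tumor_36, 125 for tumor_29, 124 for tumor_26, 108 for tumor_9514, 122 for tumor_9520, 120 for tumor_9508, 120 for tumor_33 and 125 for tumor_9529. No 2 arrays held the same values. The number of arrays limits the precision. All 15 arrays carry 1 group in the labels, spleen with leukaemia, so no group comparison was made, and spread is given as the SD over 15 tumours.

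Intensities were log2 transformed here. Of 229581 probesets, 208397 had 1 gene symbol in the platform annotation, 3965 had several and 17219 had none; only the first were used. Of 16299 symbols, 14132 were current in the GRCm38.p6 gene table, 2099 were renamed through it and 68 were not matched and kept as listed. Examples are Penk (listed as Penk1), Tfec (Tcfec), Cxcr2 (Il8rb), Adgre1 (Emr1), Kdm5d (Jarid1d) and Kdm6a (Utx). That table was used only for names, chromosome membership and gene order, since its build differs from mm9. A gene's value is the median over its probesets (median 11 per gene). A gene was called detected when its mean over all tumours exceeded the 40th percentile of all named genes (6.41), which held for 9779 genes, 9462 of them with at least 3 probesets. Split-half r is the Pearson correlation across tumours between the means of odd-ranked and even-ranked probesets, ranked by identifier.

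The tests, the 25 gene lists, the 14 pairs of lists and the rule for named genes were fixed before the data were examined. Named were the 30 detected genes with at least 3 probesets and the largest SD, and per list the 2 detected members with the highest mean and the 2 with the largest SD. Kdm6a, Jak1, Pml, Rara, Flt3, Kit, Myc and Ctsg were named in any case, as were up to 10 genes per direction past the threshold in the numbering check (none passed). Each list's median level and median SD were set against 10000 random lists of its size, for spread matched on mean level in 20 bins. List scores are the mean deviation of detected members from the 15-tumour mean, for the 19 lists with at least 4 such members, without the Hox, sex-linked and myeloid leukaemia lists. A gene in both lists of a pair was left out of both. Pearson's r and Spearman's rho were tested with two-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over 171 pairs. T cell with interferon response was not tested, as only 3 interferon genes were detected.

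Tumour numbers with 2 digits (5 tumours) and 4 digits (10 tumours) were compared as a possible batch with limma (lmFit and eBayes) and, for lists, camera with a preset correlation of 0.01. Chromosome values are the median over detected genes of the deviation from the 15-tumour median, relative to the tumour's median over all genes, against 10000 random gene sets. They used 9746 genes on 20 chromosomes. For Kdm6a and Jak1, the number of probesets in which a tumour was the lowest of 15 was ranked among detected genes with at least as many probesets. Alternatives were the mean over probesets, no filter or a 60th percentile filter on dim genes, probesets above the 25th percentile, centred or quantile normalized arrays, single tumours left out, other fits and z-scored members. Leaving out tumor_9509 and tumor_9514, also with an estimated correlation in camera, was added after the data were seen.

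Steps across many genes were tested on simulated data. In the numbering check, over 9779 genes, limma recovered 82% of 100 genes shifted by 1 log2 unit and 97% of 100 shifted by 2, with 13 other calls, and camera recovered the 1 shifted list with 0 others. The correlation step found the 1 planted pair and 0 of 170 others, over 9779 genes. The chromosome step found both shifts of 0.3 and 1 of 298 other values, over 9746 genes and 1000 random sets. Apart from the planted effects, the simulated genes varied independently of each other. The counts of other calls therefore do not cover lists or chromosomes whose genes vary together. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.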

Results

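Spleens of mice with acute promyelocytic leukaemia (APL), a leukaemia of cells blocked at the promyelocyte stage of neutrophil development, were profiled on whole-transcript exon arrays. The series held 15 arrays of 15 tumours, named by number (such as tumor_31), all from the spleen of Bl/6 Taconic mice. All 15 formed 1 group, and no array of a healthy spleen was analysed here, so no leukaemia-against-normal comparison followed from the labels. The questions addressed were therefore which genes the tumours shared at high level, which differed between tumours, and whether those differences moved together. The median deposited intensity over 229581 probesets lay between 108 and 129 on the 15 arrays. Gene values are log2 intensities, the median over the probesets of a gene, and errors are SDs over the 15 tumours unless another n is given. The labels do not say whether the tumours came from separate animals, so p-values measure the spread between these 15 arrays, part of which may be technical. The number of arrays limits the precision. Arrays correlated with each other at r = 0.928 to 0.978 across genes, and none held the values of another. The arrays of tumor_9509 and tumor_9514 stood apart: they correlated at 0.964 with each other and at no more than 0.949 with any other array.

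Granulocyte genes gave some of the highest intensities on these arrays. Levels of different genes also depend on the affinity of their probes, and there was no reference sample, so ranks of levels describe intensities and are not measures of abundance. The primary granule list holds genes of enzymes stored in promyelocyte granules and also Cebpe, a transcription factor gene. Its median level was 10.50 and exceeded all 10000 random gene lists of its size. Mpo (myeloperoxidase) stood at 12.91 ± 0.27 (SD, n = 15), at least 12.42 in every tumour, and Ctsg (cathepsin G) at 12.20 ± 0.24. The secondary granule list, made later in neutrophil development, also exceeded all random lists, with a median of 11.33. It was led by S100a8 at 12.84 ± 0.12 and S100a9 at 12.82 ± 0.18. The mature neutrophil list had a median of 8.51, above 99.83% of random lists, with Retnlg at 11.97 ± 0.69 and the chemokine receptor Cxcr2 at 9.79 ± 1.04. Ela2 is the symbol in the platform annotation for a gene of the primary granule list. At 10.28 ± 1.02, it was the 1 of the 10 detected members of that list with an SD above 1.

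Lists of cell growth genes also lay above most random lists in intensity. The lists for G2 and mitosis, for S phase, for Myc and ribosome biogenesis and for the unfolded protein response had medians of 8.89, 8.45, 9.11 and 8.98, above 99.98% or more of random lists. Mki67, the proliferation antigen, stood at 10.49 ± 0.33 and Birc5 at 9.63 ± 0.23. The replication clamp Pcna reached 12.04 ± 0.19 and the helicase subunit Mcm6 9.42 ± 0.54. Among growth genes Npm1 lay at 12.08 ± 0.20, Ncl at 11.73 ± 0.28 and Myc at 10.82 ± 0.69. The chaperones Calr and Hspa5 lay at 11.58 ± 0.29 and 11.18 ± 0.30. The hypoxia and glycolysis list exceeded 98.37% of random lists, led by Aldoa (10.82 ± 0.49) and Pgk1 (9.90 ± 0.18). The myeloid leukaemia gene list exceeded 99.31%, and its most variable members were Kdm6a and Etv6, the latter at 9.99 ± 0.59. The stem and progenitor list exceeded 96.09% of random lists, with Myb at 10.35 ± 0.40, Cd34 at 9.69 ± 0.46 and the receptor Kit at 8.83 ± 0.55.

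None of the 10 lists of other spleen cells lay above the central 95% of random lists in level. The B cell list had a median of 6.45, above 25.37% of random lists, and its brightest members Cd79a and Cd79b, parts of the B cell receptor, lay at 8.24 ± 0.60 and 8.11 ± 0.57. The level exceeded 55.44% of random lists for T cells, 5.58% for NK cells, 19.25% for the erythroid list, 43.83% for megakaryocytes and 20.68% for dendritic cells. It exceeded 70.13% for monocytes, 60.5% for red pulp macrophages and 65.69% for basophils, mast cells and eosinophils. The lowest was endothelium and stroma, above 1.67%, although Pecam1 (8.65 ± 0.61) was well detected. The interferon response list exceeded only 9.81% of random lists, with Irf7 at 6.92 ± 0.42. The Hox list exceeded 13.13%, and 7 of its 18 measured genes were detected, led by Hoxa4 at 7.81 ± 0.25. JAK-STAT targets and immediate early genes exceeded 85.27% and 91.27%, with Ccnd2 at 8.29 ± 0.71, Pim1 at 7.74 ± 0.67, Btg2 at 9.77 ± 0.68 and Dusp1 at 9.61 ± 0.66. Both measured sex-linked genes, Eif2s3y and Kdm5d, fell below the detection limit on average.

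Large differences between tumours were found in few genes. Of 9462 detected genes with at least 3 probesets, 72 (0.761%) had an SD above 1, 1021 had an SD above 0.5, and the median SD was 0.29. The most variable gene was Postn (periostin, a secreted matrix protein), at 7.68 ± 2.40, from 4.32 in tumor_9520 to 10.83 in tumor_9523. Intensities below the detection limit of 6.41, here and in the genes that follow, may be background, so no fold is given against them. Gal, the neuropeptide galanin, lay at 7.63 ± 2.18, from 4.86 in tumor_9523 to 10.51 in tumour tumor_9520. Xlr, an X-linked lymphocyte gene, lay at 8.81 ± 2.09 and was lowest in tumor_9500, at 2.92, with all other tumours at 6.45 or above. Penk, which encodes the enkephalin precursor, ranged from 5.89 to 11.31, and the serine protease inhibitor Serpina3g from 5.97 to 11.76. Ly6k, a cell surface protein gene, was above 10 in tumor_36, tumor_9509, tumor_9504 and tumor_9508 and at most 7.65 in the others. Akr1e1, an aldo-keto reductase gene, ranged from 4.34 in tumor_9514 to 8.57 in tumor_31. Ppic, a cyclophilin gene, reached 10.52 in tumor_36 from a lowest value of 5.33. The remaining genes among the 30 with the largest SD were Tceal8, Prg3, Rnase2a, Csta2, Retnla, Tfec, Fbp1, Ctla2b, Mmp8, Dab2, Saa3, AA467197, Zfp938, Prg2, Il1f9, Clec4b2, Rhoj, Lipo3, Iftap, Smpdl3a, Cybb and Muc13. For these 30 genes the agreement across tumours between separate sets of their probesets was high, with a median r of 0.975 and a lowest r of 0.882. Xlr, Rnase2a, Serpina3g, Ctla2b, Csta2, Clec4b2 and Lipo3 belong to multigene families, so probes may read relatives as well.

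Spread was largest in lists of late myeloid stages and of other blood cells. The basophil, mast cell and eosinophil list had a median SD of 0.90 among its 6 detected members, and no random list of the same brightness spread as widely. Prg2, an eosinophil granule protein, ranged from 8.34 in tumor_36 to 12.65 in tumor_33, and its relative Prg3 from 5.14 to 11.11 in the same tumours. Cpa3, a mast cell protease, lay at 10.63 ± 1.07, and Hdc, which makes histamine, at 8.59 ± 1.07. The mature neutrophil and secondary granule lists had median SDs of 0.87 and 0.52, and again exceeded all random lists. Mmp8, a neutrophil collagenase, ranged from 5.50 in tumor_9508 to 10.78 in tumor_31, and Ltf (lactoferrin) from 7.67 to 12.24 in the same tumours. Fpr1 (9.17 ± 1.52, 1 probeset) and Fpr2 (8.91 ± 1.26) sense bacterial peptides. The B cell, monocyte and immediate early lists exceeded 99.96%, 99.52% and 98.87% of random lists, with median SDs of 0.51, 0.41 and 0.43. The last of these fell within the central 95% with no filter on dim genes (95.7%), and both monocyte (96.43%) and immediate early (94.21%) lists did so with probesets above the 25th percentile. Cd55 (6.47 ± 0.78), F13a1 (9.34 ± 0.72), Fn1 (6.55 ± 0.75) and Jun (9.31 ± 0.71) were among their most variable members.

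The remaining lists lay within the central 95% of random lists of the same brightness, but the number of lists above it was 14 with the mean over probesets and 11 without tumor_9509 and tumor_9514, against 6 here. Single members still varied, among them Thy1 (8.91 ± 1.23) and Cd3d (7.60 ± 0.86) of the T cell list and Gzma (7.37 ± 1.00) of the NK list. Vcam1 (9.71 ± 0.89) and Adgre1 (7.30 ± 0.94), both of red pulp macrophages, varied as well, as did the haemoglobin gene Hbb-b1 (11.21 ± 0.94) and the platelet integrin gene Itga2b (7.89 ± 0.73). Members of the Myc and ribosome biogenesis list varied together, with a mean pairwise r of 0.61 against 0.07 for random lists, but of 0.34 without tumor_9509 and tumor_9514. The same measure was 0.59 for mature neutrophil genes, 0.45 for G2 and mitosis (0.20 after quantile normalization), 0.42 for B cell genes and 0.41 for secondary granule genes. It was 0.55 among the 3 detected interferon response genes, but -0.36 among the 2 left with probesets above the 25th percentile. Within the primary granule list it was 0.06, equal to random lists.

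Secondary granule genes and mature neutrophil genes rose and fell together across tumours. Their scores, the mean deviation of the detected members, correlated at r = 0.85 (permutation p = 3.0e-05, adjusted p = 0.0026, n = 15), with Spearman's rho of 0.77 (p = 0.0011, adjusted p = 0.0889). Both scores were highest in tumor_31 and lowest in tumour tumor_9508. No such link was found for the primary granule score, which correlated with the secondary granule score at r = -0.01 (permutation p = 0.968). Its members varied together no more than random lists (mean pairwise r of 0.06), so this score may hold no common movement to compare. The S phase and the G2 and mitosis scores correlated at r = 0.88 (p = 1.0e-05, the smallest the permutations can give, adjusted p = 0.0017), with rho of 0.83 (p = 0.00038, adjusted p = 0.0650). Of 171 pairs of 19 scored lists, 7 passed the adjusted threshold by Pearson's r, all positive, and none by Spearman's rho. At an unadjusted p under 0.05, 29 pairs passed by Pearson's r. With each tumour centred on its median over genes, only the 2 leading pairs passed (both r = 0.85, adjusted p = 0.0060). After quantile normalization only secondary granule with mature neutrophil passed (r = 0.83, adjusted p = 0.0188), while S phase with G2 and mitosis had r = 0.76 (adjusted p = 0.0889).

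The other 5 pairs joined G2 and mitosis with the unfolded protein response (r = 0.80, adjusted p = 0.0274), the Myc list with the unfolded protein response (r = 0.81, adjusted p = 0.0372) and the Myc list with hypoxia and glycolysis (r = 0.83, adjusted p = 0.0489). Mature neutrophil with immediate early genes (r = 0.73) and endothelium and stroma with S phase (r = 0.74) both had an adjusted p of 0.0489. Their rho values were 0.71, 0.58, 0.65, 0.55 and 0.73, with permutation p of 0.0037, 0.026, 0.0112, 0.0366 and 0.0026, in that order of pairs. Without the 2 tumours farthest from the median of the first score, r was 0.50, 0.41, 0.28, 0.47 and 0.56. Within the 10 tumours with a 4-digit number it was 0.86, 0.80, 0.95, 0.64 and 0.78. The first 3 pairs rest on tumor_9509 and tumor_9514, which were those 2 tumours. The 4 detected endothelium and stroma genes did not vary together (mean pairwise r of -0.15 against 0.04 for random lists). Unfolded protein response genes did so little more than random lists (0.14 against 0.10). The scores of these 2 lists may therefore hold no common movement.

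Both leading pairs kept their direction in every subset tried. For secondary granule with mature neutrophil, r was 0.70 without the 2 tumours farthest in secondary granule score (tumor_31 and tumor_9508), 0.82 within the 10 tumours with a 4-digit number and 0.84 without tumor_9509 and tumor_9514. For S phase with G2 and mitosis these values were 0.80 (without tumor_9504 and tumor_9514), 0.87 and 0.82. No pair passed adjustment in these smaller sets of 13 or 10 tumours. No correlation was computed within the 5 tumours with a 2-digit number.

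Of the 14 pairs fixed in advance 13 could be tested, and only the 2 leading pairs passed. Myc and ribosome biogenesis with G2 and mitosis had r = 0.74 (p = 0.0027, adjusted p = 0.0575; rho = 0.41, p = 0.129) and r = 0.26 without tumor_9509 and tumor_9514. B cell and T cell scores had r = 0.47 (p = 0.0775; rho = 0.38, p = 0.172). Primary granule with stem and progenitor had r = -0.38 (p = 0.166; rho = -0.24, p = 0.396), and with G2 and mitosis r = 0.32 (p = 0.246; rho = 0.32, p = 0.243). The other 7 pairs that did not pass, primary with secondary granule included, had r between -0.26 and 0.11.

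**Figure D1:**
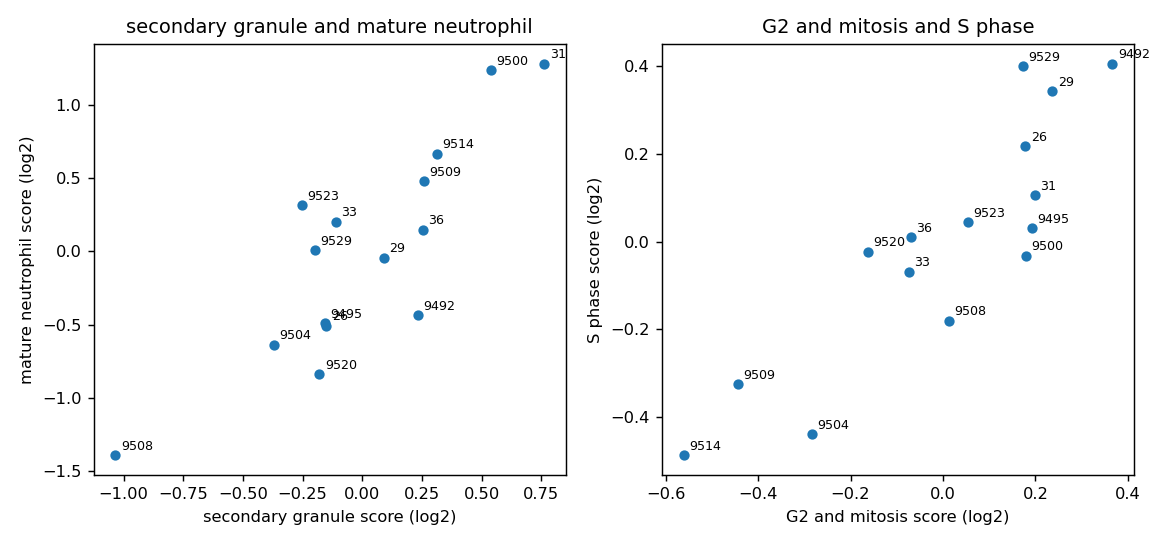
Scores of 15 tumours (points, labelled by tumour number) for secondary granule against mature neutrophil genes (left) and for G2 and mitosis against S phase genes (right), in log2 units. The tumour tumor_9508 is lowest and tumor_31 highest on both axes at the left (r = 0.85); at the right r = 0.88.

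Kdm6a, an X-linked gene for a histone H3 lysine demethylase, and Jak1, a cytokine receptor kinase, were chosen in advance because alterations of both have been described in mouse APL. Kdm6a (listed as Utx in the platform annotation, 34 probesets) lay at 6.76 ± 1.03, but its values were not spread evenly. It was 4.94 in tumor_9500, 5.25 in tumor_26, 5.28 in tumor_9495 and 5.42 in tumor_9520, and between 6.92 and 8.22 in the other 11. The gene values of those 4 tumours lie below the detection limit of 6.41, which was set on gene means, and may be background, so no fold is given. The gap in intensity between both ranges, which this limit also affects, was matched or exceeded by the largest gap of 24 of the 9462 detected genes with at least 3 probesets, Kdm6a included. The signal was below the 15-tumour median in 34 of the 34 probesets in tumor_9495 and in 33 in each of tumor_9500, tumor_26 and tumor_9520. In tumor_9500 probeset 4607037 remained at 9.33, the highest value of that probeset in any tumour. Probeset 4959743 lay at 6.64 to 7.48 in those 4 tumours and at 9.46 to 10.28 in the others. For probeset 5380850 these ranges were 6.99 to 7.27 and 8.16 to 9.225. The other probesets fell below 6.41 in some or all of the 4 tumours. The tumour tumor_9500 was the lowest of all tumours in 14 probesets, tumor_26 in 10, tumor_9495 in 7 and tumor_9520 in 2. Among 390 detected genes with at least as many probesets, this share ranked 2nd in tumor_9500, 1st in tumor_26 and tumor_9495 and 119th in tumour tumor_9520.

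Jak1 (28 probesets) lay at 8.96 ± 0.27, from 8.42 in tumor_9514, an array that stands apart, to 9.41 in tumor_9529, and its largest gap was 0.24. This range of 0.99 was 0.53 after quantile normalization and 0.66 without tumor_9509 and tumor_9514. Pml and Rara are joined in the fusion that defines human APL; Rara lay at 7.75 ± 0.48 and Pml lay between 6.48 and 7.61 (SD 0.32). Flt3, a receptor kinase gene, was below the detection limit on average at 6.29 ± 0.57, but reached 8.07 in tumor_9504 while the other tumours lay between 5.68 and 6.79. Kit was lowest in tumor_9514 (7.80) and highest in tumor_29 (9.98), and Myc was extreme in the same tumours (9.15 and 11.77).

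**Figure D2:**
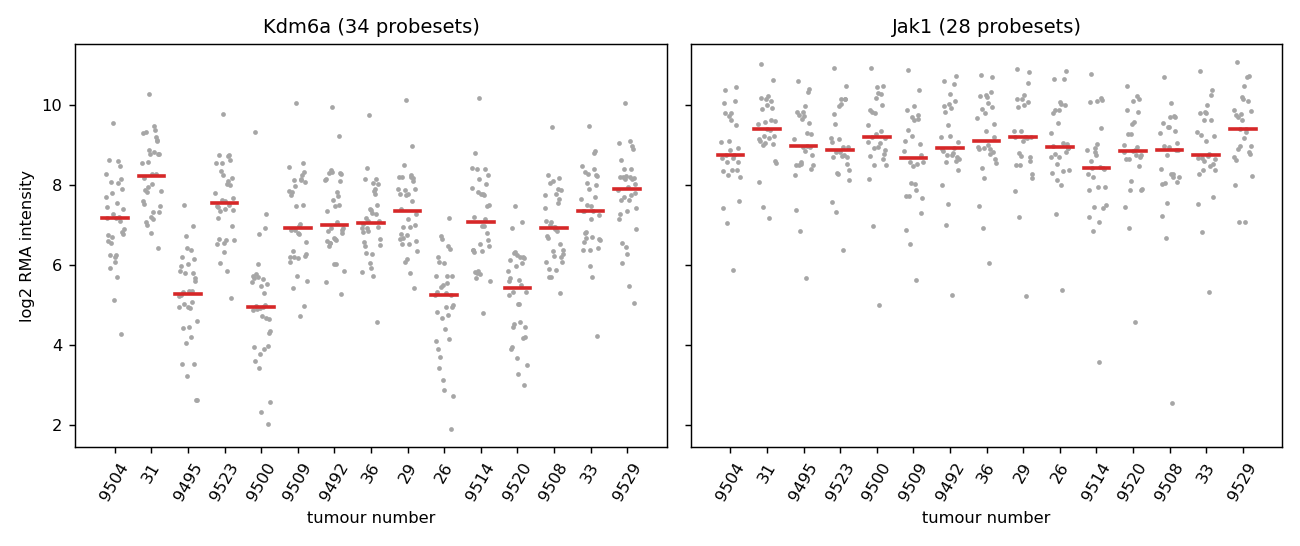
Log2 intensity of each probeset (grey points) and the gene value, their median (red bars), by tumour number for Kdm6a and Jak1. Kdm6a lies at 4.94 to 5.42 in tumor_9500, tumor_26, tumor_9495 and tumor_9520 and at 6.92 or more in the others; Jak1 stays between 8.42 and 9.41.

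Genes on whole chromosomes deviated together in single tumours. Values are the median deviation of a chromosome's detected genes from the 15-tumour median, relative to the tumour's median over all genes. The highest value was that of chromosome 16 in tumor_9492, 0.29 or 1.23-fold over 295 genes, 78.6% of which were above the tumour's median. Chromosome 14 in tumor_9529 stood at 0.24, and chromosome 6 at 0.23 in tumor_9523, 0.21 in tumor_31, 0.21 in tumor_9509 and 0.13 in tumor_9514. In tumor_9509 and tumor_9514, the arrays that stand apart, chromosome 6 was high only relative to a low median over all genes (-0.23 and -0.17). Its deviation from the 15-tumour median was -0.02 and -0.04 there. Each tumour named here for chromosome 6 was also low in chromosome 19, as listed below. Chromosome 1 stood at 0.19 in tumor_9529 and 0.18 in tumor_29, chromosome 5 at 0.18 in tumor_9504 and chromosome 16 at 0.18 in tumour tumor_9529. Chromosome 10 stood at 0.13 in tumor_33 and 0.12 in tumor_9504, in which chromosome 5 stood at 0.11 and 0.18. Chromosome 19 was low in tumor_9492 (-0.28), tumor_9523 (-0.25), tumor_9509 (-0.24), tumor_9514 (-0.24) and tumor_31 (-0.19), among them both arrays that stand apart. It lay above all random sets in 7 of the others, tumor_26 (0.14), tumor_9500 (0.13), tumor_9495 (0.13), tumor_9520 (0.12), tumor_36 (0.09), tumor_9504 (0.06) and tumor_9508 (0.05).

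Chromosomes 15, 2 and X had been fixed in advance; gain of chromosome 15 and loss within chromosome 2 are known in mouse APL. Chromosome 15 was above all random gene sets in tumor_26 (0.14), tumor_9495 (0.12), tumor_9492 (0.09), tumor_9520 (0.06) and tumor_33 (0.03). It was below all of them in tumor_36 (-0.14), tumor_9509 (-0.12, an array that stands apart), tumor_9523 (-0.10), tumor_31 (-0.08) and tumor_9500 (-0.07). In tumor_31 its deviation from the 15-tumour median was 0. It was low there only relative to that tumour's median over all genes (0.08). Chromosome 2 was lowest in tumor_36, at -0.14, where 4 equal parts in gene order stood at -0.01, -0.07, -0.46 and -0.20. It was slightly high in tumor_9523 (0.06) and tumor_9492 (0.05). The X chromosome lay below all random sets in tumor_9504 (-0.12) and tumor_9520 (-0.06), in the latter no longer when the sets were matched on level. Of 300 values, 75 lay outside all 10000 random sets, 40 above and 35 below, with at least 2 in every tumour. Each value belongs to a single tumour and has no replicate. Random sets treat genes as independent, so small deviations outside them carry little weight, and a shift shared by most tumours cannot be seen against their median.

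**Figure D3:**
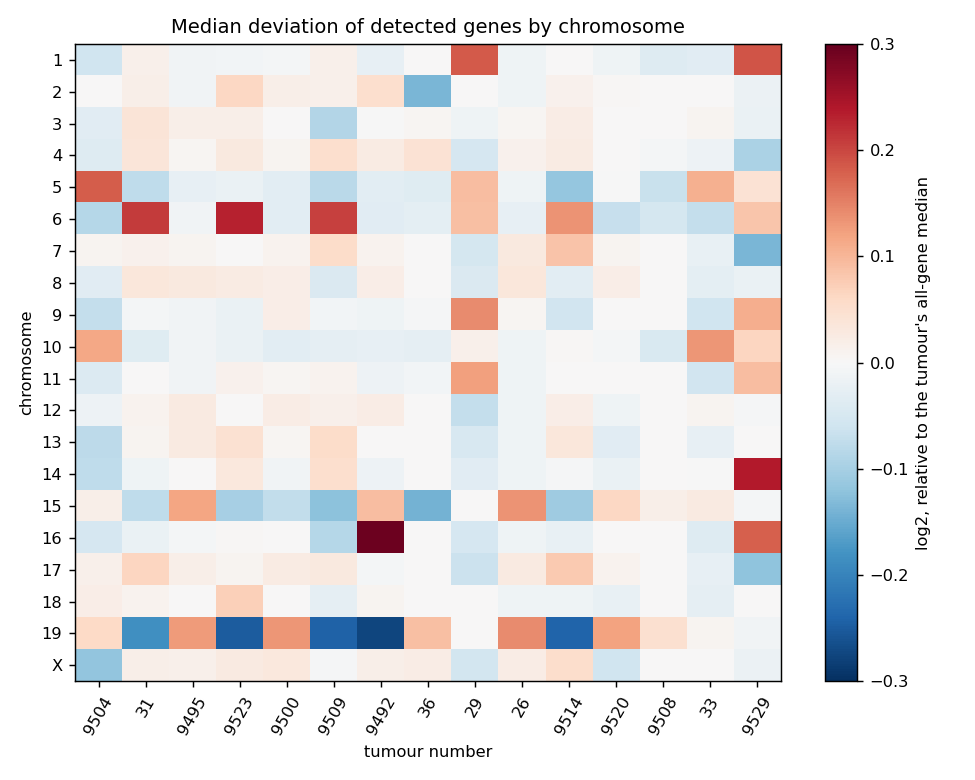
Median deviation of detected genes by chromosome (vertical axis) and tumour number (horizontal axis), in log2 units relative to the tumour's median over all genes; red is higher and blue lower. Chromosome 16 in tumor_9492 (0.29) is the highest value and chromosome 19 in the same tumour (-0.28) the lowest.

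Windows of 25 neighbouring detected genes, chosen after the chromosome values were seen, placed the low part of chromosome 2 in tumor_36. There 17 windows in a row (425 genes, from Nup35 to Edn3) lay below 0, 10 of them below all 1000 shuffles of gene order. Their median was -0.36, or 0.780-fold, and the lowest, from Ndufaf5 to Cst7, -0.60. The 13 other windows of the chromosome lay between -0.08 and 0.06. In tumor_9500, 5 windows in a row (125 genes, from Cdca7 to Srp14) lay below 0, with a median of -0.17. Of these only the window from Slc35c1 to Eif3m, at -0.39 with 24 of its 25 genes lower, lay below all shuffles. Of 5685 window values, 47 lay outside all shuffles, 34 below and 13 above.

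**Figure D4:**
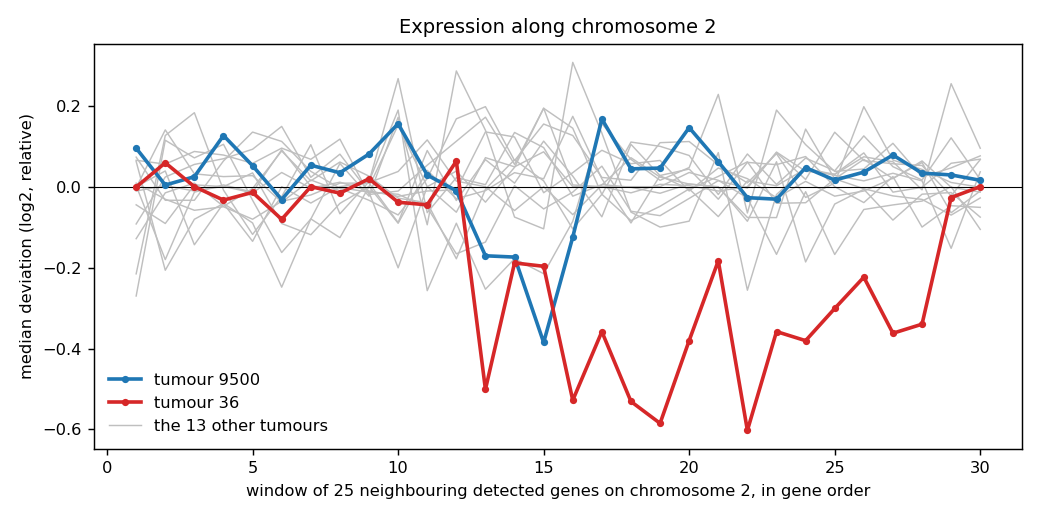
Median deviation (log2, relative to the tumour's median over all genes) in windows of 25 neighbouring detected genes along chromosome 2, in gene order, with 1 line per tumour. The tumour tumor_36 lies below 0 over 17 windows in a row, with a lowest value of -0.60, and tumor_9500 reaches -0.39 in 1 window.

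The tumours are numbered in 2 series, 10 with 4-digit and 5 with 2-digit numbers, which were checked as a possible batch. No gene passed an adjusted p of 0.05 among 9779 detected genes in limma's test, and 227 had an unadjusted p under 0.05. That is a smaller share of the genes than the 0.05 expected on average without any difference. Tumours with a 4-digit number were lower as a set in the lists of red pulp macrophages, S phase and hypoxia and glycolysis and higher in JAK-STAT targets, each with an adjusted p of 0.0480 in limma's camera with a preset correlation. None of the 4 held with an estimated correlation (adjusted p = 0.589, 0.729, 0.729 and 0.560 in that order). None was left without tumor_29. Without tumor_9509 and tumor_9514, 4 lists passed again, but of the first 4 only that of red pulp macrophages (adjusted p = 0.0133 by camera). The others were secondary granule (0.00093), mature neutrophil (0.0015) and immediate early genes (0.0112), all lower in 4-digit tumours. With an estimated correlation none of these 4 passed in the 13 tumours left (adjusted p = 0.522 for each). Adjusted over the list alone, 3 genes passed among 24 lists, 1 each in the macrophage, immediate early and hypoxia lists. These were Vcam1, an adhesion molecule, which differed by -1.23 ± 0.33 (SE) between 4-digit and 2-digit tumours (adjusted p = 0.0119 over its list and 1.00 over all genes by limma). The others were Ier2, an immediate early gene, at -0.41 ± 0.10 (0.0101 over its list) and Bnip3, a hypoxia-induced gene, at -0.52 ± 0.16 (0.0498 over its list), both named after their values were seen.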

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

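Leaving out tumor_9509 and tumor_9514 together and doing so with an estimated correlation in camera were the alternatives chosen only after the data were seen.

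For 357 results, 2539 alternative values were computed. The 9 lists with a level above the central 95% of random lists numbered 8 or 9 under all 7 alternatives tried. No gene passed in the numbering check by limma under any alternative, while 138 to 468 genes had an unadjusted p under 0.05. The 72 genes with an SD above 1 numbered 51 to 96 under the alternatives, with 22 to 29 of the 30 most variable genes shared, and the 75 chromosome values outside all random sets 65 to 89. Of the alternative values of named genes, 525 mean levels moved by less than the SD and 525 SDs by less than 1.5 times, and 25 of each by more. Of the pairs past the threshold beyond both leading ones, 54 alternative values still passed, and 80 kept their direction but no longer passed.

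The 6 lists with a spread above the central 95% of random lists became 14 with the mean over probesets and 11 without tumor_9509 and tumor_9514. Immediate early genes were no longer among them with no filter on dim genes (above 95.7% of random lists), nor were immediate early genes (94.21%) and monocytes (96.43%) with probesets above the 25th percentile. The 7 correlated pairs became 12 with the mean over probesets, 2 with tumours centred on their median, 1 after quantile normalization, and 0 within 4-digit tumours, without tumor_9509 and tumor_9514 or without the 2 farthest tumours. Leaving out 1 tumour gave 2 to 10 pairs. It gave 2 without tumor_9500, tumor_9509, tumor_29 or tumor_9514, 3 without tumor_9504 and 4 without tumor_26, tumor_9520 or tumor_9529. Smaller sets of tumours have less power; the other causes were not tested.

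Secondary granule with mature neutrophil (r = 0.85) no longer passed within 4-digit tumours (0.821), without tumor_9509 and tumor_9514 (0.835) and without the 2 farthest tumours (0.701), each time with fewer tumours. Leaving out 1 tumour gave 0.790 to 0.895. G2 and mitosis with S phase (r = 0.88) no longer passed in the same sets (0.868, 0.815 and 0.802) nor after quantile normalization (0.761), and the cause was not tested for the last. Leaving out 1 tumour gave 0.838 to 0.901. G2 and mitosis with the Myc list (r = 0.74) passed with the mean over probesets (0.764), the stricter filter on dim genes (0.731), the means of both numbering series removed (0.736) and the B cell score held constant (0.751). Leaving out 1 tumour gave 0.59 to 0.80, and it passed without tumor_9492 (0.763); the cause was not tested.

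The 4 lists in the numbering check by camera became 1 with no filter on dim genes, 1 with tumours centred, 1 after quantile normalization, 0 with an estimated correlation, with all tumours or without tumor_9509 and tumor_9514, and 0 with fry. Leaving out single 2-digit tumours gave 0 to 5, with 0 without tumor_29 and 2 without tumor_36 or tumor_26; the cause was not tested. The range of Jak1 over tumours (0.99) was 0.529 after quantile normalization and 0.661 without tumor_9509 and tumor_9514, its lowest values being in those left out. Chromosome 6 in tumor_9520 (-0.07) stood at 0 with no filter on dim genes; the cause was not tested. The mean pairwise r of interferon response genes (0.55, 3 genes) was -0.36 with probesets above the 25th percentile, which left 2 genes. Background correction and scan dates were not varied. Signal over background limits dim genes, whose changes an array compresses.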

Other observations

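The pair correlations of variable genes and 2 tests on Kdm6a (failing probesets, dimmer arrays), the test on other spleen cells and both counts of splits were chosen only after the results were seen.

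Several of the most variable genes moved against or with each other. Among all 435 pairs of the 30 genes with the largest SD, 37 passed an adjusted permutation p of 0.05, 19 positive and 18 negative, and 118 passed unadjusted. Without tumor_9509 and tumor_9514, 27 passed, and within the 10 tumours with a 4-digit number 15. Postn (periostin) ran against Serpina3g at r = -0.91 (p = 2.0e-05, adjusted p = 0.0029; rho = -0.95, p = 1.0e-05, the smallest possible, adjusted p = 0.0022) and against Gal (galanin) at r = -0.91 (p = 5.0e-05, adjusted p = 0.0052; rho = -0.88, p = 2.0e-05, adjusted p = 0.0029). Without the 2 tumours farthest in Postn, r was -0.88 in both, and within 4-digit tumours -0.91 (adjusted p = 0.0464) and -0.90 (adjusted p = 0.0587). Gal ran with Serpina3g at r = 0.90 (p = 6.0e-05, adjusted p = 0.0052; rho = 0.85, p = 0.00014, adjusted p = 0.0087; 0.90 without the 2 farthest and 0.91 within 4-digit tumours). The eosinophil granule genes Prg3 and Prg2 ran together at r = 0.94 (p = 1.0e-05, adjusted p = 0.0022; rho = 0.98, p = 1.0e-05, adjusted p = 0.0022; 0.94 in both subsets).

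Of 2 measured Y-linked genes, Eif2s3y was 9.44 in tumor_9500 and 8.95 in tumor_33, 5.10 to 5.91 in tumor_26, tumor_29 and tumor_9529, and at most 4.08 in the others. Kdm5d was 7.09 in tumor_9500, 7.09 in tumor_26 and 6.82 in tumor_33, and at most 5.75 in the others.

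Kdm6a was low in tumor_9500, tumor_26, tumor_9495 and tumor_9520. A few failing probesets would move neither the median over 34 probesets, by which these tumours were noticed, nor most single probesets, and at least 97.1% of them lay below their own median in each. In the deposited values these 4 arrays were not dimmer as a whole: the lowest median deviation of all detected genes among them was 0. RMA normalizes between arrays, so this cannot show whether the arrays were dimmer before it. A lower signal over the whole stretch of the 10 nearest detected genes would lower their median, but its lowest value was -0.094. A shorter stretch cannot be excluded by that median. Of these neighbours, Maoa, Fundc1 and Rp2 stood at -1.22, -0.31 and -0.37 in tumor_26 and at -0.80, 0.11 and 0.54 in tumor_9495. In tumor_9500 they stood at 0.13, 0.03 and 0.28, and in tumor_9520 at 0.63, -0.33 and 0. Maoa was also low in tumor_9523 (-1.44), where Kdm6a was not. Lower abundance of Kdm6a transcripts may therefore underlie the pattern; this is a hypothesis found on the same data, and no biological explanation was tested because the labels give 1 group.

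Chromosome-wide deviations appeared in single tumours. Brightness of the genes does not account for most: 69 of 75 values (92%) lay outside all random sets matched on level. Scaling between arrays does not either, as 71 of 75 (94.7%) remained outside after quantile normalization. Single stretches of genes cannot be excluded. Of the 75 values, 67 (89.3%) had the same sign in all 4 equal parts in gene order, but parts of any size count. Chromosome 2 in tumor_36 is among the 67, although its last 2 parts (-0.46 and -0.20) carried most of its value. Altered chromosome number may underlie part of the deviations, but no DNA measurement was analysed here. No biological explanation was tested, and coordinated expression of neighbouring genes stays open. Whether the many values of tumor_9529 (11), tumor_29 (10) and tumor_9504 (9) share 1 cause within each array was not tested.

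Arrays of tumor_9509 and tumor_9514 stood apart. Their distribution of intensities is not the whole cause, as after quantile normalization they still held 2 of the 2 largest loadings on the first component (0.60 and 0.67, next 0.19). Noisier probesets may contribute: the within-gene residual SD was at least 0.512 in both and 0.311 to 0.415 in the other arrays. A different mix of cells stays open. Relative to the array's median, 4 of 8 lists of other spleen cells lay above 0 in both. Among these were erythroid (0.64 and 0.41) and B cell (0.85 and 0.20, with Cd79a at 9.55 and 8.89). Below 0 in both lay the lists of red pulp macrophages (-0.51 and -0.32) and of basophils, mast cells and eosinophils (-0.10 and -0.48). No list lay below by more than the SD of its score in both. The mature neutrophil (0.71 and 0.84) and Myc (-0.40 and -0.58) lists moved apart. Residuals of both arrays correlated at 0.321, above all other pairs (-0.33 to 0.16), so a shared probeset-level effect of handling or of RNA stays open, and no biological explanation was tested.

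In the numbering check, 0 genes passed in the real split of the tumours into 10 and 5. All 100 splits reach that by construction, so this count decides nothing; the highest of the others gave 11. For lists, 40 of 100 splits gave at least its 4, and the highest of the others gave 9. Chance cannot be excluded for the 4 lists.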
